A study of Homo sapiens with 6 samples.

How the data were processed

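Polyadenylated RNA of the human osteosarcoma line U2OS was sequenced 48 hours after transfection with a control RNA, a mimic of the microRNA miR-571 or an inhibitor of it. Each of the 3 groups had 2 libraries, 6 in all, which the submitters call biological replicates. Per the labels' protocols the libraries were made with a stranded kit after oligo-dT selection. Groups were taken from the sample titles. The description of the second inhibitor library names the workbook of the mimic comparison, against its title and its transfection label, and the title was followed.

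The values used here come from a pair of comparison tables, mimic against control and inhibitor against control. Per the file headers, the authors' deposited tables give for each row the mean of the control group and of the treated group on a log2 scale, the log2 fold change (treated minus control), an unadjusted p-value from each of 5 tools (DESeq2, edgeR, a t-test, EBSeq and limma), and an ensemble p-value with its adjusted p-value. How the authors combined the 5 p-values is not given in the sources used here. Values of single libraries were not analysed here. No SD from replicate values, no replicate check of single genes and no new fit was therefore possible. The means are printed as the authors' means. The inhibitor table has 1 row per gene (34495 rows). The mimic table has 1 row per transcript (88933 rows). The submitters' processing notes name STAR 2.5.1a, HTSeq and DESeq and the build GRCh38.p7. The tables carry UCSC known-gene identifiers, and 3.63% of 21302 gene starts lay within 1000 bases of the GRCh38 annotation, so no coordinate of the tables is printed. Positions come from GENCODE 29 on GRCh38, matched by gene symbol.

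The deposited log2 means behave as log2(value + 1) of a scaled whole count. Rows at 0 in both groups (13091 genes and 34664 transcripts) had no p-value, which left 21404 genes and 54269 transcripts tested by the authors. The authors' adjusted ensemble p equals a Benjamini-Hochberg adjustment over all rows, untested ones included. The smallest steps between low values give what 1 read was worth in a library, and from these the libraries held approximately 27000000 to 31700000 reads in features. These depths are inferred from the deposited values. A log2 fold change on this scale understates the change of rows with few reads.

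Choices made before the data were examined were the comparisons, 30 gene lists, the seed-site test and the rule for named genes. The planned fit needed counts per library, and the plan's fallback, the authors' values with no new test, was used. The main call is the authors' ensemble adjusted p under 0.05. As an alternative chosen after seeing the data, the unadjusted p-values of each of the authors' 5 tools were adjusted here by the Benjamini-Hochberg method over the tested rows, and edgeR, the tool planned for counts, is used to name genes, with the number of the 5 tools that passed beside it. In the report "rose" and "fell" refer to an adjusted p under 0.05 by the authors' edgeR values. The named genes were the 10 largest rises and the 10 largest falls among protein-coding genes that passed with an average log2 CPM of at least 1, up to 3 passing members of each list by smallest adjusted p, the 5 smallest ensemble p-values where fewer than 5 rows passed, up to 5 shared calls in each direction, and always ZNF141, CDT1, GMNN, CREB1, MYC, CDKN1A and MDM2. Of the genes this rule names, 1 is not reported here. The part of the rule that asked for both treated libraries to lie beyond both controls could not be applied. List members named for the mimic were chosen after their values were seen, as were the 8mer genes named with the largest falls.

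To bring the mimic to gene level, the transcripts' means were returned to the linear scale, summed per gene and taken back to log2. The control libraries are the same in both tables. Over 1392 genes with 1 transcript row, their control means differed by a constant 1.67 (quartiles 1.67 and 1.67), which is a difference of scale. A gene sum was used when its control value matched the control mean of the gene table within 0.1 after that shift, which held for 10974 of 12722 genes above the floor (86.3%). This check sees only the control side. A gene whose mimic libraries disagree on the isoform appears too low, and 93 gene sums were lower by a log2 of 1 or more against 17 higher. Of 2994 genes with 1 transcript row, which are free of this, 34 were lower and 12 higher by as much, so it does not explain all of the imbalance. Values of such genes are given as an alternative. The tables were normalized separately, so mimic and inhibitor were not compared with each other directly.

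For each list, the median log2 fold change of members above a floor of 2 CPM was placed among 10000 random lists of equal size drawn from 20 bins of mean expression. A percentile below 2.5 or above 97.5 is called outside the random range. Members of a pathway vary together and random genes do not, so the percentile describes these libraries and is not a test across replicates. Lists with fewer than 5 members above the floor were given no median. The mitochondrially encoded list matched no symbol in the tables. A further 3 lists (small nucleolar RNA hosts, cytosolic aminoacyl-tRNA synthetases and nonsense-mediated decay factors) were added after seeing the data, and their results are in the closing section. Transcript GC content was known for 86.8% of inhibitor genes and 87.0% of mimic genes, and random lists matched on both expression and GC content (10 bins each) were an added alternative.

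For the seed test, the mature sequence UGAGUUGGCCAUCUGAGUGAG was found from position 61 of the annotated 96-nucleotide MIR571 precursor. Protein-coding genes with an annotated 3' UTR (the longest of each gene) were searched, 11304 of the inhibitor comparison and 9533 of the mimic comparison. Genes with the 7mer-m8 site CCAACUC, complementary to nucleotides 2 to 8, were set against genes without the 6mer CAACUC, and the difference of their medians was ranked among 100 of the 104 other heptamers with the same bases.

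On simulated data 100 genes were raised and 100 lowered by a log2 of 1. The gene sums of the mimic comparison (10974 genes) gave medians of 0.98 and -1.02. All transcripts of a gene were shifted together there. The simulation thus does not test the error from libraries that disagree on the isoform. Of unshifted random lists of 25 genes 6% fell outside the random range in the inhibitor setting (11304 genes). Without a shift the difference of simulated seed-site genes (9533 genes) was 0.00, at percentile 91 of shuffled heptamers. With a shift of -0.10 put on them it was -0.10, at percentile 0. The size of that change was fixed in advance, because the shift was added to every site gene. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.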

Results

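RNA of U2OS cells, a line derived from an osteosarcoma, was compared 48 hours after transfection with a miR-571 mimic, a miR-571 inhibitor or a control RNA, with 2 libraries in each of the 3 groups. A mimic supplies the mature microRNA to the cell, and an inhibitor is an oligonucleotide that binds it. The gene of the microRNA, MIR571, lies on chromosome 4 from 350157 to 350252 on the plus strand (GRCh38), within ZNF141 (337814 to 384864) and outside the exons of its annotated basic coding transcripts. The deposited values imply approximately 27000000 to 31700000 reads in features per library. They are group means, so no value below carries an SD. ZNF141 is listed at 0 in both groups of the inhibitor comparison in the authors' deposited table, and its mimic value was not analysed here.

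The comparison of the inhibitor with the control asks which RNAs differ when an inhibitor of miR-571 is supplied. The clearest group was the ATF4 and amino acid response list, genes induced when amino acids are short or the endoplasmic reticulum is under stress. By the edgeR values of the authors' deposited table, 19 of its 26 measured members rose, 0 fell and 7 did not pass. The cystine transporter gene SLC7A11 rose from a mean log2 value of 8.19 to 9.74 in the authors' deposited table, 2.92-fold (4 of 5 tools). The serine synthesis enzyme gene PSAT1 rose from 12.21 to 13.09, 1.84-fold, and TRIB3, a pseudokinase gene that ATF4 induces, from 8.66 to 9.84, 2.26-fold (4 of 5 tools each, the authors' deposited table). The list median was 0.44, at percentile 100 of random lists, whose central range ran from -0.13 to 0.02. Adjusted over the list alone, 22 members rose and 1 fell by edgeR, and 20 passed by the authors' ensemble p.

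Further genes were among the largest rises by edgeR in the authors' deposited table. CHAC1, which degrades glutathione and is itself a member of the ATF4 list, rose by a log2 of 0.99 (4 of 5 tools). SESN2, a leucine sensor, rose by 0.96 and CTH, which makes cysteine, by 0.85 (4 of 5 tools each). INHBE rose by 1.48, ARFRP1 by 1.09, DHRS2 by 1.06 and DDR2, a collagen receptor gene, by 0.87 (3 of 5 tools each, the authors' deposited table). The control mean of INHBE (5.09) was below the log2 value of 2 CPM (5.64). SLC7A11 lies on chromosome 4 from 138164097, TRIB3 on chromosome 20 from 362835 and PSAT1 on chromosome 9 from 78297143 (GRCh38).

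The largest falls by edgeR in the authors' deposited table were MAGED4 (log2 fold change -2.01), GNB3 (-1.39), WNK4 (-1.29), PPP1R10 (-1.20) and C1S (-1.16). FAM184A (-1.11), ADM5 (-1.07), DKK3 (-1.04), LRRC39 (to 0.501 of the control level) and RHOV (-0.99) followed in the authors' deposited table. PPP1R10, a regulatory subunit of protein phosphatase 1, passed by 4 of 5 tools and LRRC39 by 1. MAGED4, GNB3, WNK4 and FAM184A passed by 3, and C1S, ADM5, DKK3 and RHOV by 2. The unadjusted ensemble p was 0.077 for ADM5 and 0.069 for RHOV. With the inhibitor the mean log2 values of WNK4 (5.54), DKK3 (5.59) and LRRC39 (5.35) were below that of 2 CPM (5.64). C1S (5.65) was close to it. MAGED4 has a near-identical neighbouring copy, so its reads may have been split by the authors' counting.

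Genes of cholesterol synthesis fell. By edgeR in the authors' deposited table, 12 of 24 measured members were lower, 0 higher and 12 did not pass. HMGCS1, which makes the precursor of mevalonate, fell from 12.49 to 11.69 (log2 fold change -0.80, 4 of 5 tools), INSIG1, which retains the sterol sensor in the endoplasmic reticulum, from 11.85 to 11.20 (-0.65) and IDI1 from 12.02 to 11.45 (-0.57, 3 of 5 tools each). The list median was -0.30, at percentile 0 of random lists. Adjusted over the list alone, 15 members fell by edgeR and 13 passed by the ensemble p.

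Chaperones of the heat shock response fell as well. By edgeR in the authors' deposited table, 8 of 13 members were lower, 1 was higher and 4 did not pass, with a list median of -0.23 at percentile 0.02. HSPA8, the constitutive cytosolic chaperone gene, fell from 13.91 to 13.15 (-0.76), and HSPA1B, its inducible relative, from 12.70 to 11.81 (-0.88, 4 of 5 tools each, the authors' deposited table). HSPE1 fell by 0.42 on the log2 scale (3 of 5 tools). HSPA4L was the member that rose, by 0.32. HSPA1B shares near-identical sequence with HSPA1A, so its count is uncertain. Adjusted over the list alone, 9 members fell and 1 rose by edgeR and 9 passed by the ensemble p.

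Of 37 subunits of respiratory complex I, 14 fell by edgeR in the authors' deposited table, led by NDUFB7 (-0.53), NDUFA1 (-0.35) and NDUFB3 (-0.36), and 0 rose, while 4 passed by DESeq2 and 7 by EBSeq. The complex I median was -0.19 at percentile 0, with 18 members lower by edgeR and 9 passing by the ensemble p when adjusted over the list alone. Of 18 glycolysis genes 8 fell, among them PKM (-0.43), PGAM1 (-0.37) and PFKP (-0.40, 3 of 5 tools each, the authors' deposited table). The glycolysis median was -0.16 at percentile 0.76, which moved to 3.78, inside the random range, when lists were matched on GC content too, and 12 members were lower by edgeR and 11 passed by the ensemble p when adjusted over the list alone. Of 18 hypoxia genes 3 fell in the authors' deposited table, NDRG1 (-0.40), BNIP3 (-0.35) and JMJD6 (-0.31), with a median of -0.15 at percentile 1.26 and 3 lower by edgeR and 3 passing by the ensemble p when adjusted over the list alone. Of 76 ribosomal protein genes 11 fell, with RPS14 (-0.31), RPS26 (-0.30) and RPL7A (-0.25) leading in the authors' deposited table. The ribosomal median was -0.16 at percentile 0, where the random range ran from -0.13 to -0.05. Genes of like expression were thus lower too, and only part of this median is particular to the list. Adjusted over the list alone, 40 members were lower by edgeR and 0 passed by the ensemble p. Genes rich in GC were lower in general: the median log2 fold change ran from 0.12 in the tenth of genes with the lowest GC content (37.0%) to -0.15 in the tenth with the highest (64.3%).

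The p53 target list had a median of 0.12, at percentile 99.9, but its members moved both ways. After the trend over GC content was removed its median was 0.00, at percentile 83.3 and inside the random range, although random lists matched on GC content left it at percentile 100 when rounded, so the rise of this list depends on how GC content is treated. By edgeR in the authors' deposited table SESN2 and GADD45A (log2 fold change 0.47), both also known as amino acid stress genes, rose with 2 others, while CDKN1A, the cell cycle inhibitor gene, fell from 10.73 to 10.34 (-0.39, 3 of 5 tools) and BTG2 fell by 0.59. Adjusted over the list alone 7 rose and 3 fell by edgeR and 7 passed by the ensemble p. Homologous recombination and Fanconi anaemia genes had a median of 0.06 at percentile 98.0, which was 71.5 with GC matching. BLM (0.31), BRCA2 (0.53, unadjusted ensemble p 0.059) and RAD51AP1 (0.27) rose and FANCI (-0.26) fell in the authors' deposited table. Over all genes 4 of 28 were higher and 1 lower. Adjusted over the list alone, 8 were higher and 2 lower by edgeR, and 2 passed by the ensemble p.

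Within the unfolded protein response list HERPUD1 (0.59) and XBP1 (0.44) rose and the chaperone cofactor genes MANF (-0.44) and SDF2L1 (-0.35) fell by edgeR in the authors' deposited table, and the median of -0.03 was inside the random range. Replication and cell cycle lists stayed inside the random range, except that the G1/S list, with a median of 0.00 at percentile 86.4, was at 0.02 and percentile 98.2 once the trend over GC content was removed. Of 24 licensing genes DTL (0.43) and MCM10 (0.35) rose and MCM7 (-0.37) fell in the authors' deposited table. Of 28 G1/S genes 3 rose and 2 fell, with PRIM1 at 0.47, LIG1 at -0.34 and RRM2 at -0.30. Of 30 mitotic genes HMMR (0.34) rose and 3 fell, CDC25B (-0.28) and AURKB (-0.23) among them (the authors' deposited table). The checkpoint list had PPP2R2A (0.28) and TIPIN (0.29) higher and RAD9A (-0.26) lower. The unadjusted ensemble p was 0.079 for SDF2L1, 0.077 for CDC25B and 0.098 for RAD9A. Adjusted over each list alone, the numbers higher and lower by edgeR were 2 and 2 for the unfolded protein response, 2 and 1 for licensing, 3 and 2 for G1/S, 2 and 3 for mitosis and 5 and 1 for the checkpoint. By the ensemble p, adjusted in the same way, 4 passed for the unfolded protein response, 4 for licensing, 8 for G1/S, 2 for mitosis and 0 for the checkpoint.

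Further lists held few calls by edgeR in the authors' deposited table. Immediate early genes had EGR1 (0.38) and JUN (0.18) higher and FOSB (-0.72), MYC (-0.33) and IER2 (-0.24) lower. The mesenchymal list had CDH2 (0.33), ZEB1 (0.35) and ZEB2 (0.32) higher and VIM (-0.25) and SNAI1 (-0.64) lower in the authors' deposited table. Apoptosis regulators had PMAIP1 (0.35) and BIRC2 (0.23) higher and CASP2 (-0.23) and BID (-0.28) lower. ATG7 (0.39) rose and ATP6V0D1 (-0.34) fell in the autophagy and lysosome list. TAGLN (-0.84), ID2 (-0.22) and NOG (-0.61) fell among TGF-beta targets, ARHGEF17 (-0.48) among YAP targets, COL6A2 (-0.32) among matrix genes, IFITM1 (-0.32) among interferon-stimulated genes, and DDX5 (-0.29) and DDX17 (-0.24) in the microRNA machinery (the authors' deposited table). The end joining, NF-kB, NRF2, replication-dependent histone, epithelial and haematopoietic lists had 0 members passing over all genes. Adjusted over each list alone, edgeR gave 2 higher and 4 lower for immediate early genes, 3 and 2 for the mesenchymal list, 2 and 2 for apoptosis, 1 and 1 for autophagy and lysosome, 1 and 4 for TGF-beta targets, 1 and 3 for NRF2 targets, 0 and 2 for the microRNA machinery and 0 and 1 each for YAP targets, matrix and interferon genes. By the ensemble p, adjusted in the same way, 2 immediate early genes, 4 of the mesenchymal list and 1 apoptosis regulator passed, and 0 of each of the other lists in this paragraph. All of these medians were inside the random range, and too few epithelial (3) and haematopoietic (2) genes were above the floor for a median.

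**Figure D1:**
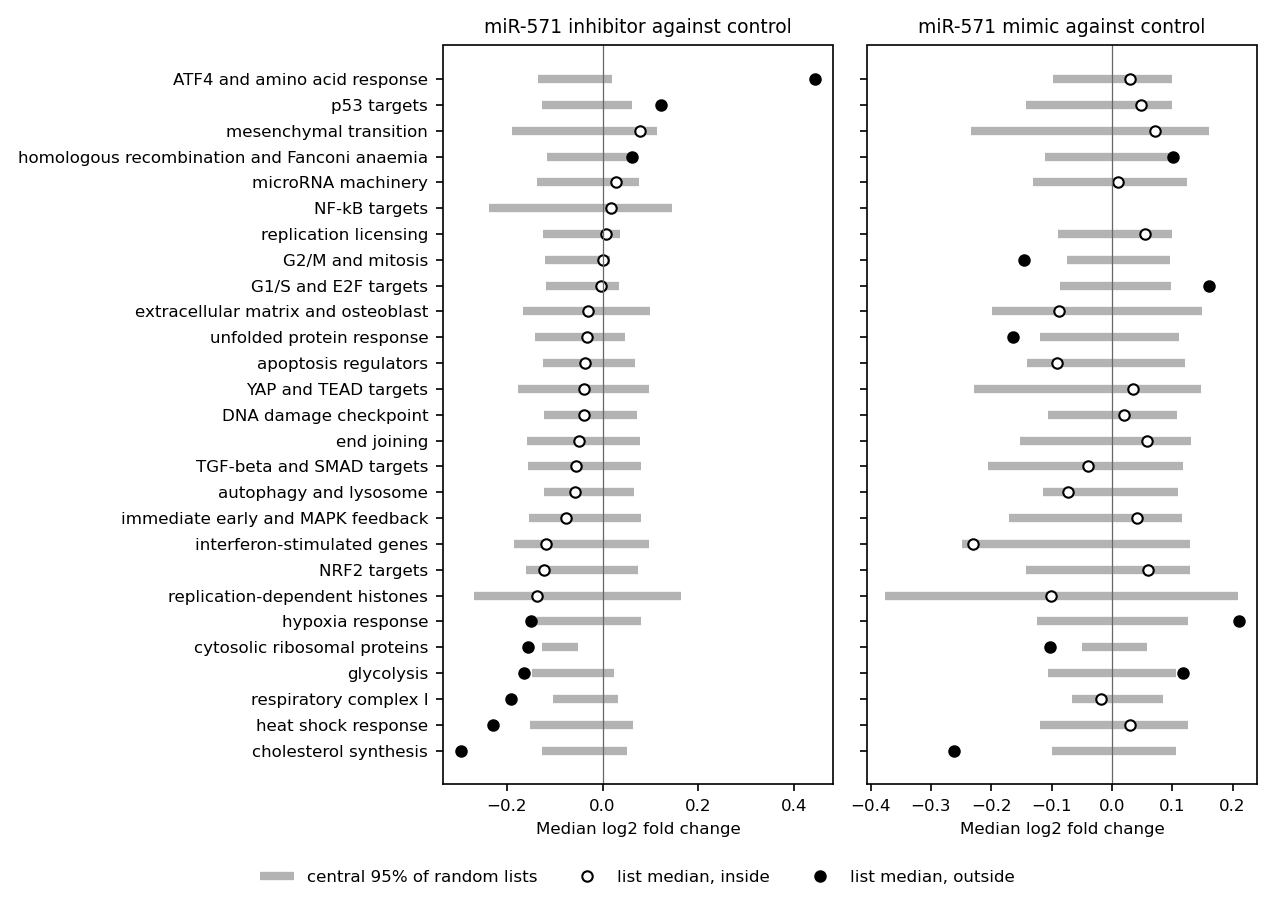
Median log2 fold change of each gene list fixed in advance (points) in the inhibitor comparison (left) and the mimic gene sums (right), with the central 95% of 10000 expression-matched random lists as grey bars and filled points outside it. The ATF4 and amino acid response list stands at 0.44 with the inhibitor and 0.03 with the mimic, and the cholesterol synthesis list is at -0.30 and -0.26.

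By the authors' ensemble test 0 of 21404 genes passed in the inhibitor comparison. The smallest adjusted p was 0.0983, shared by 10 genes of the authors' deposited table, of which TXNIP (log2 fold change 0.68), PSAT1 (0.88), HSPA8 (-0.76), SESN2 (0.96) and SNRNP70 (-0.59) had the smallest ensemble p-values and are named as not passing. At an unadjusted ensemble p under 0.05 there were 1960 genes, 937 of them higher. The single tools of the authors' deposited table differed widely after adjustment, with 1780 genes by edgeR (699 higher), 1090 by EBSeq (533 higher), 864 by DESeq2 (509 higher), 37 by limma (28 higher) and 0 by the t-test, and 620 genes passed by 3 or more tools (336 higher). Falls outnumbered rises by edgeR, with 1081 genes lower, and rises outnumbered falls by DESeq2, with 355 lower, so the balance of direction depended on the tool. Of the other genes fixed in advance, CDT1 (0.13), GMNN (0.08), CREB1 (0.00) and MDM2 (0.18) passed by 0 of 5 tools, and MYC fell by 2 of 5 (the authors' deposited table).

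The comparison of the mimic with the control asks which RNAs differ when miR-571 is supplied. RNAs with a match to the miR-571 seed in their 3' UTR were lower. The 929 genes with a 7mer-m8 site CCAACUC had a median log2 fold change of -0.11 in the gene sums made from the authors' deposited table, against 0.00 in 7149 genes without the 6mer. The difference of -0.12 was below that of all 100 shuffled heptamers, the lowest of which gave -0.06. The 237 genes with an 8mer site CCAACUCA were lower by 0.16, and 73.8% of them had a value below 0. Genes with 2 or more sites had a median of -0.15, against -0.11 for those with 1 site. Sites in the coding sequence went with a difference of -0.08, also at percentile 0. In 218 site genes with 1 transcript row, which need no summing, the difference was -0.12.

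Of the genes fixed in advance, GMNN, whose product geminin restrains the licensing factor CDT1, has 1 site in its 3' UTR (chromosome 6, gene from 24774931 to 24786099, GRCh38) and was 1.44-fold lower in the mimic gene sums (13.21 to 12.68). CREB1, which encodes a cAMP-responsive transcription factor, has 1 site in its coding sequence and 0 in its 3' UTR and was 1.27-fold lower (chromosome 2, 207529737 to 207603431). CDT1 (0.06), MYC (0.43) and CDKN1A (-0.04) have 0 sites. MDM2 has 1 site, and its gene sum did not match the gene table. The main transcript of each of these 6 genes passed by 0 of 5 tools in the authors' deposited table. Among the 8mer genes the largest falls, chosen after their values were seen, were SAMD12 (-1.14), CREG2 (-1.01), HIST1H2BD (-0.98), LRRC32 (-0.91) and SS18L2 (-0.83). In the mimic group SAMD12 (7.42), CREG2 (7.45) and LRRC32 (7.10) were near or below the log2 value of 2 CPM (7.27). SAMD12 (3 transcript rows) and HIST1H2BD (2) are sums, which appear too low where libraries disagree on the isoform.

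The same test on the inhibitor gave no difference that stood apart. The 1136 genes with a 7mer-m8 site had a median of -0.01, and 8364 genes without the 6mer one of -0.05. The difference of 0.04 was at percentile 58 of shuffled heptamers, whose central range ran from 0.01 to 0.06.

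**Figure D2:**
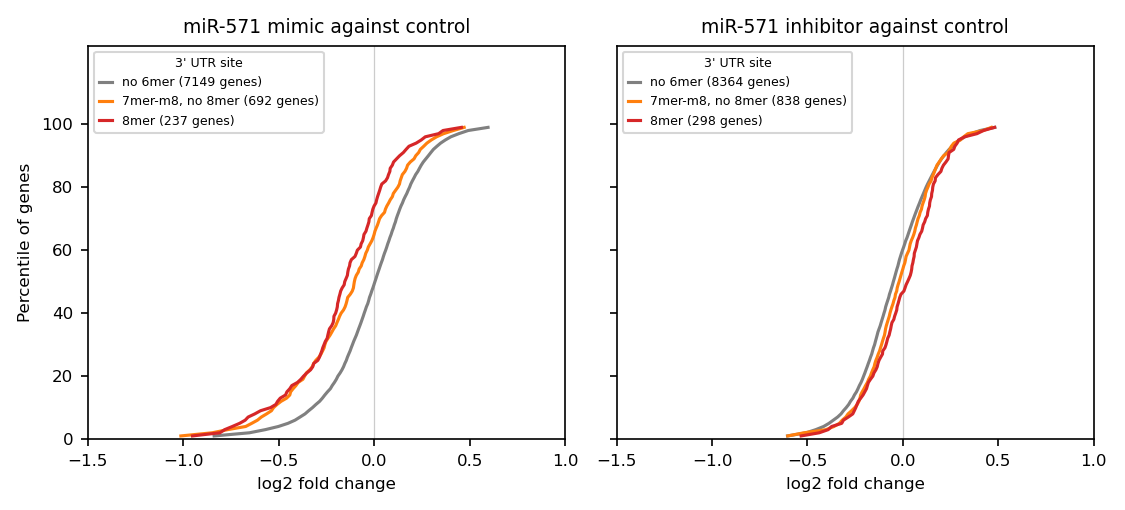
Cumulative distribution of log2 fold changes (x axis) as percentiles of genes (y axis) for genes with no 6mer, with a 7mer-m8 but no 8mer, and with an 8mer site in the 3' UTR, in the mimic gene sums (left) and the inhibitor comparison (right). The 237 genes with an 8mer lie to the left with the mimic, where 73.8% are below 0.

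Among the gene lists of the mimic comparison, 8 of 26 medians of the gene sums lay outside the random range, and no transcript chosen as a member's main transcript passed by edgeR in the authors' deposited table, so the following are levels and not calls. Minor transcripts of 3 list members passed. Cholesterol synthesis was lowest, with a median of -0.26 at percentile 0 and 18 of 21 members below 0, such as MVD (-0.52), DHCR7 (-0.42) and IDI1 (-0.42). The unfolded protein response list had a median of -0.16 at percentile 0.23, with HSPA5 at -0.66, MANF at -0.61 and DNAJB11 at -0.50. Mitotic genes had a median of -0.15 at percentile 0.02, with 25 of 29 below 0, among them CDC25C (-0.78), CDCA8 (-0.61) and CDC25B (-0.54). In the 6 mitotic genes with 1 transcript row the median was -0.07, at percentile 12.2. Ribosomal proteins had a median of -0.10 at percentile 0.02, and 5.52 in the 26 with 1 row.

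G1/S genes were higher with the mimic, with a median of 0.16 at percentile 100 when rounded and 21 of 26 members above 0, PRIM1 (0.52), CHAF1B (0.46) and E2F2 (0.36) foremost. Hypoxia genes had a median of 0.21 at percentile 99.9, with EGLN3 (0.52), PFKFB4 (0.51) and BNIP3 (0.47), and glycolysis genes one of 0.12 at percentile 98.8, with the glucose transporter gene SLC2A1 at 0.82 and hexokinase gene HK2 at 0.64. The homologous recombination list was at 0.10, percentile 97.8, which was 89.7 with GC matching, with BRCA2 at 0.70. The ATF4 and amino acid response list was at 0.03 and the heat shock list at 0.03, both inside the random range. The other lists were inside the range, with medians from -0.23 for interferon-stimulated genes to 0.07 for the mesenchymal list. The interferon list was at percentile 3.70, and at 1.77 with the trend over GC content removed.

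By the authors' ensemble test 0 of 54269 transcripts passed in the mimic comparison. The smallest adjusted p was 0.0768, for 1 transcript each of CTAGE5, LPXN and GRHL1 in the authors' deposited table, all of them lower, and PPIE followed at an ensemble adjusted p-value of 0.115. At an unadjusted ensemble p under 0.05 there were 4514 transcripts, 2313 of them higher. By single tools of the authors' deposited table, EBSeq passed 1741 transcripts, with 303 by the t-test, 106 by edgeR (58 higher), 53 by DESeq2 and 0 by limma. All 106 edgeR calls were in genes with several transcript rows, with a median absolute log2 fold change of 8.77, whereas the gene sums of the 82 calls with a usable sum differed from the control by a median of 0.18 in size. Only 2 of them met the expression rule: a transcript of the helicase gene HLTF rose by 1.98 with a gene sum of 0.13, and a transcript of IP6K2 fell by 6.67 in the authors' deposited table with a gene sum of -0.45 that did not match the gene table.

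Across 10900 genes the log2 fold changes of mimic and inhibitor were correlated, with Pearson's r of 0.34 and Spearman's rho of 0.34, and genes are not independent replicates. Both comparisons use the same control libraries. Unchanged groups simulated against shared controls gave an r of 0.50. This value follows from giving the 3 groups equal spread, so the observed r is not judged against it. The covariance was 0.0234, against 0.00789 simulated, where the spread of a library was taken from the authors' t-test p-values and is approximate. Splitting the controls needs single libraries and was not done, so part of the excess may come from the shared controls. Fold changes of both comparisons also declined with GC content (Spearman's rho -0.43 with the inhibitor and -0.14 with the mimic). The simulation held no such trend, and its share of the excess was not tested. Hypoxia and glycolysis genes lay below the random range with the inhibitor and above it with the mimic. For glycolysis with the inhibitor this was lost when lists were matched on GC content too (percentile 3.78). The difference between the reagents was not tested.

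Calls of genes with the inhibitor were set beside calls of single transcripts with the mimic. Of 19093 genes in both tables, 9 calls by edgeR in the authors' deposited table had the same direction in gene and transcript and 5 the opposite, where 4.76 and 4.95 follow from the sizes of the lists. By EBSeq there were 149 and 44, where 46.5 and 46.7 follow (the authors' deposited table). These chance values leave out the shared controls, which by themselves favour the same direction, and a simulated value for calls was not made, so no excess over them is read as a shared effect. Those with the smallest larger p in the same direction were ELAC2, MYO9B, UBAP2L, SH3PXD2A and CKAP2L, and in the opposite direction ZMYM1, MYO9B, STX16, FOXRED2 and LZTR1 (the authors' deposited table). MYO9B and STX16 stand in both because different transcripts moved in opposite ways. The direction of a transcript is not that of its gene: the mimic gene sums of ELAC2 (0.03), UBAP2L (0.13) and SH3PXD2A (0.26) were above 0 where the inhibitor values of the authors' deposited table fell (-0.41, -0.24 and -0.30), and CKAP2L had a sum of -0.33 against a rise of 0.33. Only MYO9B of these 5 had a gene sum (-0.43) on the side of its inhibitor value (-0.32). LZTR1, listed as opposite, had a sum of -0.08 and an inhibitor value of -0.23 in the authors' deposited table. Mimic and inhibitor were not set against each other directly, since their tables were normalized separately.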

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

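No paired analysis was possible because the deposited tables give group means only, with no value per library. For the same reason the alternatives named before the data were seen, normalization, low-count filter, pseudocount, model, samples in the fit, replicate block, leaving out a library, split controls and estimated correlation, were not run. All alternatives below except the seed-site types, the coding sequence, the length-matched background and the fold-change threshold were chosen after seeing the data. The number of calls depended on the tool. Against 0 by the ensemble, the inhibitor comparison had 864 by DESeq2, 1780 by edgeR, 1090 by EBSeq and 37 by limma, and the mimic comparison 3 by the ensemble p over tested rows, 53 by DESeq2, 106 by edgeR, 303 by the t-test and 1741 by EBSeq, all from the authors' p-values. The edgeR calls of the inhibitor numbered 141 with an absolute log2 fold change of at least 1 as well. Only 34 genes at or above the floor of 2 CPM changed by as much, called or not. Most of the 141 were thus below that floor. Calls shared in the same direction numbered 3 by DESeq2, 9 by edgeR and 149 by EBSeq (46.5 by list size, with 44 opposite) against 0 by the ensemble. Of the 20 genes named for the inhibitor by edgeR, 7 passed by limma and 0 by the t-test. The cause of these differences was not tested.

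Seed-site genes of the mimic stayed below the random range in all 7 alternatives, with differences from -0.16 (8mer) to -0.08 (coding sequence) and -0.12 with the GC trend removed. Those of the inhibitor stayed inside it in all 6, from -0.01 to 0.07. The correlation of fold changes was 0.30 at 4 times the expression floor and 0.37 in genes with 1 transcript row. With 1 row per gene, 2 of 11 mimic lists lay outside the random range, against 4 of the same lists in the gene sums; fewer members were measured. Matching on GC content moved the homologous recombination and glycolysis lists of the inhibitor, and the homologous recombination list of the mimic, inside the range, and kept 25 lists of each on their side. At 4 times the floor the mesenchymal list of the inhibitor (percentile 99.2) and the interferon list of the mimic (2.49) moved outside, and the homologous recombination list of the mimic (97.48) moved inside. Reads limit the precision of low rows, where 1 read is a large step on the log2 scale.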

Other observations

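Chosen after the result was seen were the tests of the control libraries on the amino acid response and cholesterol lists, the test of GC content on the cholesterol list in both comparisons, the test of isoforms, the stress test of the host genes, and the lists of host genes, tRNA synthetases and decay factors. The ranking of all heptamers was chosen once the seed test of the report was known, before the ranks were seen. Cytosolic aminoacyl-tRNA synthetases, which load tRNAs with amino acids, were above the random range as a list with the inhibitor. By edgeR in the authors' deposited table, 11 of 20 rose, 2 fell and 7 did not pass, with a median of 0.22 at percentile 100, and 14 passed by the ensemble p adjusted over the list alone. TARS (log2 fold change 0.61), CARS (0.58), MARS (0.51), SARS (0.48) and YARS (0.47) rose by 4 of 5 tools each, while QARS (-0.25) and HARS (-0.28) fell. The ATF4 list also holds synthetase genes, namely CARS, SARS, GARS, AARS and WARS. With the mimic the median of 19 synthetases was 0.12 at percentile 98.4, with 14 above 0, and 0 of their 80 transcripts passed by edgeR in the authors' deposited table. Control libraries low for these genes would raise both comparisons, and this was not excluded.

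Spliced hosts of small nucleolar RNAs carry these RNAs in their introns. With the inhibitor the median of 17 host genes was 0.13 at percentile 99.9, with C6orf48 (0.62), SNHG1 (0.59) and SNHG7 (0.47) higher by edgeR in the authors' deposited table and SNHG12 (-0.30) lower. Of the 17 hosts 6 rose, 1 fell and 10 did not pass. GC content was known for 1 of them, so this percentile has no check against the GC trend. With the mimic the median of 15 was -0.17 at percentile 0.22, with SNHG9 (-0.43), ZFAS1 (-0.32) and GAS5 (-0.31) lowest. In the 5 host genes with 1 transcript row the mimic median was also -0.17, at percentile 5.39, inside the random range, and 0 of 53 host transcripts passed by edgeR in the authors' deposited table. The difference between the comparisons was not tested. Many such RNAs are substrates of nonsense-mediated decay, and weaker decay with the inhibitor may raise them. The RNAs of 7 decay factors, which the pathway itself keeps low, had a median of 0.05 at percentile 89.8, and resampling the 7 gave an upper bound of 0.18 against a random range that ends at 0.11, so this remains open. The bound set before the result, a median inside or below the random range, argued against weaker decay, and the resampling was added after the result was seen. A stress response that raises host genes as well is not decided by their own percentile of 99.92, since the list was drawn up from these data.

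The link between the mimic and the miR-571 seed was tested without choosing the heptamer. All heptamers found in at least 50 3' UTRs were ranked by how strongly the mean fold change of genes with them differed from that of other genes, after removing trends over GC content and 3' UTR length. The site CCAACUC ranked 1 of 16149, with a mean difference of -0.12 that was 12.2 standard errors below 0, and CAACUCA ranked 2. In coding sequences the same heptamers ranked 1 and 2 of 16368. In 3' UTRs, matches to windows that begin at nucleotide 4 or later of miR-571 had no such shift, with differences between -0.02 and 0.00. With the inhibitor CCAACUC ranked 8388 of 16218 in 3' UTRs, and 16134 of 16377 in coding sequences, towards higher values. That was the highest of the miR-571 windows in coding sequences, where the lowest ranked 9857. The trend over coding length was not removed in either comparison. Set against shuffled heptamers in coding sequences, the same site was at percentile 89 with the inhibitor, inside the random range. The ranks found with the mimic are what repression through the seed by the transfected mimic would give. The genes are not replicates, and the test says nothing about which single gene is a direct target.

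The rise of the amino acid response list with the inhibitor was weighed against 3 explanations. Control libraries that happened to be low for these genes would raise the list with the mimic too, but its median there was 0.0305 against 0.44. After removing the trend over GC content the inhibitor median was 0.49, still at percentile 100, which argues against GC content as the cause. Direct relief of miR-571 sites would need sites in the members. Of 25 searched members 1 (4%) has a 7mer-m8 site in its 3' UTR, against a mean of 7.18% in lists matched on 3' UTR length. Sites in the coding sequences of the members were not counted, so relief through those was not tested. A response of the cells to the inhibitor oligonucleotide itself, or an indirect effect of miR-571, stays open, as does any difference between the inhibitor cultures and the others in medium or density.

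The cholesterol synthesis list was lower with both reagents. Its medians, -0.30 with the inhibitor and -0.26 with the mimic, are what control libraries high for these genes would give, since both comparisons use them. Matching on GC content left the list at percentile 0 in both, which argues against the GC trend as the whole cause. With the trend removed the medians were -0.20 with the inhibitor and -0.22 with the mimic. A response shared by cells given either reagent would give the same values and stays open.

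The largest transcript changes with the mimic may come from reads shared between isoforms. Among transcripts above the floor in either group, 3 of 3079 in genes with 1 row (0.097%) changed by a log2 of 3 or more. In genes with several rows 1720 of 22307 did (7.71%). This floor lets a row enter through its higher group alone. With the floor put on the mean of both groups, 143 of 22870 transcripts of all genes (0.63%) changed by as much. Of 82 edgeR calls in the authors' deposited table whose gene sum could be used, 81 had a gene sum that moved by under 1. Real switches between isoforms of genes that make several stay open, since genes with 1 row cannot show them.

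The decline of fold changes with GC content was steeper with the inhibitor, where Spearman's rho across 11323 genes was -0.43, than with the mimic (-0.14 across 9551 genes); the difference was not tested. Among random lists matched on GC content the inhibitor lists of ribosomal proteins, complex I and cholesterol synthesis were each at percentile 0. This argues against the trend as their whole cause. In the same lists glycolysis was at 3.78, inside the random range. The glycolysis median of -0.16 did not change there, and its place did because the random range moved from -0.15 to 0.02 down to -0.17 to -0.04. With the trend removed the glycolysis median was -0.11, at percentile 10.0. The trend may thus account for part of its fall, and the rest is not set apart from random lists. The medians of ribosomal proteins, complex I and cholesterol synthesis were then -0.14, -0.17 and -0.20, from -0.16, -0.19 and -0.30. These stayed below the random range, and the trend may account for part of them too.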
